A study of Homo sapiens with 6 samples.

How the data were processed

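Human THP-1 cells and M2 macrophages were fixed with formaldehyde and their chromatin was sheared by sonication, per the labels' protocols. Libraries were made for YY1, H3K27ac and input, 1 of each per cell type, and sequenced as paired ends on an Illumina instrument, per the same protocols. Of these 6 libraries, the 2 H3K27ac libraries are represented here by 1 peak list each. The YY1 and input libraries were not analysed here. Bowtie2, MACS2 version 2.1.0 and the genome build hg19 are named in the submitters' processing notes, without the settings, and whether the input libraries served as control in peak calling is not given in the sources used here. The peak lists carry no header and were read in the standard narrowPeak column order, which was checked on the values. Because the notes name hg19, gene positions of GRCh38 were not used with these lists. Peaks reached beyond the highest GRCh38 gene end on 14 of 23 chromosomes. A peak can lie past the last gene of a chromosome in either build, so this does not tell the builds apart.

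The fold enrichment of each peak is a ratio at the summit over the local background, deposited by the authors as the peak caller gave it. The -log10 p and -log10 q of each peak are likewise the authors' deposited values, and the lowest -log10 q was 1.31 in the M2 list and 1.30 in the THP-1 list, just above that of a q of 0.05. The score column deposited by the authors is the whole part of 10 times the -log10 q and was not used further. These values belong to each peak and were used to describe, rank or filter peaks within a list. The number in the name of the first peak is 2468 in the M2 list and 1253 in the THP-1 list, and the 2467 and 1252 lower numbers are not used here. What those entries were, and why the numbering starts there, is not known. From the first peak of chromosome 1 onwards, at position 28676 in the M2 list and 28515 in the THP-1 list, 0 numbers are missing in either list, so the counts and shares are of an unbroken run of entries that may not be the whole of what was called. In 1 M2 peak the summit lies outside the peak. The Y chromosome was left out of all values.

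Peaks were compared by overlap with bedtools 2.31.1, with at least 1 bp in common counted as shared. The share expected from covered length alone was the mean over 100 circular shifts of the other list along each chromosome, with a fixed seed. Stitched regions join peaks of a list that lie within 12500 bp of each other. Those with at least 10 peaks were counted, and the covered length inside the same bounds was taken from the other list. Covered length was used for ranking because peak lists hold no reads. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, since peaks of a library are not independent replicates. Ratios of peak numbers per chromosome carry intervals of the same kind. No p-value was computed, because each group has 1 library and nothing measures the spread between libraries.

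The definition of shared peaks, the dense regions, the rule for named regions and the first group of other settings listed at the end were fixed before the data were examined. The rule for named items called for genes, with a fallback for files without usable gene positions, which applied here. It names the 5 regions per list of highest fold enrichment that are in 1 list only, and the 5 stitched regions per list with the most covered sequence, whatever their number of peaks. Of the planned results, 4 were not made, because no hg19 annotation or sequence was used here. They were the location of peaks in genes, the genes with a promoter peak, the comparison of gene lists and the share of summits with a sequence motif.

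Depth was recovered from the lists. The usual MACS2 relations, fold enrichment as the pileup plus 1 over the background plus 1 and a Poisson p-value, were solved together for each peak. With the ChIP pileup scaled by 0.842 in the M2 list and not scaled in the THP-1 list, they gave a whole number of fragments, within 0.02, for 99.98% of M2 and 100% of THP-1 peaks. A typical other scale gave 5.85% and 7.4%. A single solution was found for 54945 M2 peaks (97.4%) and 30522 THP-1 peaks (97.1%), and statements on background use these. The lowest background, taken as the genome-wide level, was 1.94 fragments in the M2 list and 1.77 in the THP-1 list. If a control library set the background, the scales correspond to 1.19 ChIP fragments per control fragment for M2 and 0.678 for THP-1. Summits held 9 to 611 fragments in the M2 list and 8 to 687 in the THP-1 list. These numbers are an inference from 2 columns of the lists and not counts the authors gave. On simulated peaks with known answers the pileup was right in 100% of single solutions, and 97.3% of peaks had a single solution when simulated without scaling and 96.2% with a scale of 0.75. The overlap step was also tested on simulated peaks.

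The other settings fixed in this way were a -log10 q of at least 10, merging of entries within 1000 bp, an overlap of at least 50% of the shorter peak, the summit inside a peak of the other list, lists of equal length (31444 or 15722 peaks of highest -log10 q) and stitching within 5000 or 20000 bp. Settings added after the data were seen were peaks with a background of at most 2 times the lowest, sharing within 1000 bp, leaving out a stretch of chromosome 8 from 86 to 87 Mb, and shifts of 100 to 1000 kb for the share expected by chance. Runs of M2-only peaks were counted along each chromosome and compared with 1000 random reorderings within chromosomes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.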

Results

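The series profiled chromatin in THP-1 cells, a human monocytic leukaemia line, and in M2 macrophages, the alternatively activated state of these phagocytes. From which cells the macrophages were made is not given in the sources used here. Each cell type had 1 sequencing library for the transcription factor YY1, 1 for H3K27ac and 1 for input DNA, 6 libraries in all. H3K27ac is an acetylated form of histone H3 that marks active promoters and enhancers. The values reported here come from the 2 H3K27ac peak lists, 1 per cell type, and the YY1 and input libraries were not analysed here. The question put to these lists was which regions carried H3K27ac in the monocytes, in the macrophages or in both. With 1 library per cell type no difference has a replicate check, so no test between the cell types was made and no p-value is given. Intervals are exact 95% binomial intervals for shares of peaks, and they cover counting error only. Positions are in hg19, and the Y chromosome was left out of every value. Regions are named by coordinates, because no hg19 gene annotation was used here, and no peak was assigned to any gene, IL6 and YY1 included.

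The lists give no read counts, but the number of fragments over each summit could be recovered from the fold enrichment and the p-value of the peak. A median of 40 fragments lay over an M2 summit (interquartile range 23 to 77) and 39 over a THP-1 summit (23 to 72). By the same recovery the M2 H3K27ac library held 1.47 times as many fragments as the THP-1 library, if the effective genome size was the same and the fragment length was the width of the narrowest peaks. Because the M2 pileup was scaled by 0.842, the genome-wide coverage that entered the calls was only 1.10 times that of THP-1.

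H3K27ac covered more of the genome in the M2 list than in the THP-1 list. The M2 list held 56420 peaks and the THP-1 list 31444, a ratio of 1.79. M2 peaks covered 61.3 Mb and THP-1 peaks 28.0 Mb, a ratio of 2.19. The median M2 peak was 743 bp wide (interquartile range 461 to 1391) and the median THP-1 peak 661 bp (459 to 1052). The widest M2 peak spanned 26100 bp and the widest THP-1 peak 12744 bp. On the authors' own scale, each list against its own background, the median fold enrichment was 5.42 in the M2 list and 3.67 in the THP-1 list. These medians do not by themselves measure a stronger M2 signal. At shared pairs of peaks the recovered fragments over the summit, relative to the coverage of the library, had a median ratio of M2 to THP-1 of 0.939 (interquartile range 0.649 to 1.38). The pairs hold only sites called in both lists and leave out the 35520 M2-only peaks, so the ratio does not speak for those. With peaks kept only at a -log10 q of at least 10, the lists held 34097 M2 and 13241 THP-1 peaks, and the ratio was 2.58. The higher local background at THP-1 summits, given below, lowers the -log10 q of a peak with the same fragments. The cut can remove more THP-1 peaks for that reason, so the higher ratio is no further evidence of a larger M2 list.

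M2 peaks outnumbered THP-1 peaks on each of the 23 chromosomes. The ratio was lowest on chromosome 17, with 2425 M2 and 1501 THP-1 peaks (1.62, interval 1.51 to 1.72). It was highest on chromosome 14, with 1653 M2 and 778 THP-1 peaks (2.12, interval 1.95 to 2.32). Chromosome 12 followed at 2.08, and chromosome 1 stood near the low end at 1.65.

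In the full lists most THP-1 peaks overlapped an M2 peak, while most M2 peaks overlapped no THP-1 peak. Of the THP-1 peaks, 23683 overlapped an M2 peak by at least 1 bp, which is 75.3% (interval 74.8 to 75.8), and 7761 did not. Of the M2 peaks, 20900 overlapped a THP-1 peak, which is 37.0% (36.6 to 37.4), and 35520 did not. Shifting the other list along each chromosome 100 times gave a mean overlap of 3.70% for THP-1 peaks and 2.03% for M2 peaks, so the observed shares were 20.4 and 18.2 times those from covered length alone. The sequence inside peaks of both lists came to 18.4 Mb, which is 65.8% of the THP-1 and 29.97% of the M2 covered length. Part of the contrast between the shares follows from list length, since similar numbers of shared peaks are divided by 31444 THP-1 and 56420 M2 peaks. In lists of the 31444 peaks of highest -log10 q, 59.6% of THP-1 and 49.0% of M2 peaks were shared. The THP-1 share fell below 50% in 2 settings. With the 15722 peaks of highest -log10 q in each list, 48.7% (47.9 to 49.4) of THP-1 and 40.5% of M2 peaks were shared, and among peaks whose recovered background was at most 2 times the lowest of their list, a choice made after the data were seen, the THP-1 share was 45.5% (44.2 to 46.8).

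Shared M2 peaks were wider than M2-only peaks, with a median of 1197 bp against 591 bp, and had a higher median fold enrichment, 6.33 against 5.00. Shared THP-1 peaks were also wider than THP-1-only peaks, 712 bp against 536 bp, but their median fold enrichment was lower, 3.49 against 4.05. The 15927 pairs in which an M2 peak and a THP-1 peak overlapped each other and no further peak had summits a median of 78 bp apart, and 74.1% of the pairs had summits within 200 bp. The M2 peak was the wider in 69.1% of these pairs, with medians of 1079 bp for M2 and 694 bp for THP-1.

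The share of M2 peaks with a THP-1 counterpart rose with peak strength. It was 18.6% (17.6 to 19.6) in the decile of M2 peaks of lowest -log10 q and 71.5% (70.3 to 72.7) in the decile of highest. In that highest decile 1606 of 5642 M2 peaks, or 28.5%, overlapped no THP-1 peak. In the THP-1 list 93.2% (92.3 to 94.0) of the highest decile overlapped an M2 peak, and 214 of 3144 peaks, or 6.81%, did not. M2 peaks of higher -log10 q were also wider, with a median of 398 bp in the lowest decile and 2243.5 bp in the highest. In deciles by width the M2 share rose from 16.3% to 72.4%, so strength and width were not told apart. Ranked by fold enrichment, the M2 share again rose, from 24.7% to 55.4%. The THP-1 share instead was highest in the decile of lowest fold, at 96.6% (95.9 to 97.2), fell to 65.4% (63.7 to 67.1) in the eighth decile and was 76.9% (75.4 to 78.3) in the highest.

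**Figure D1:**
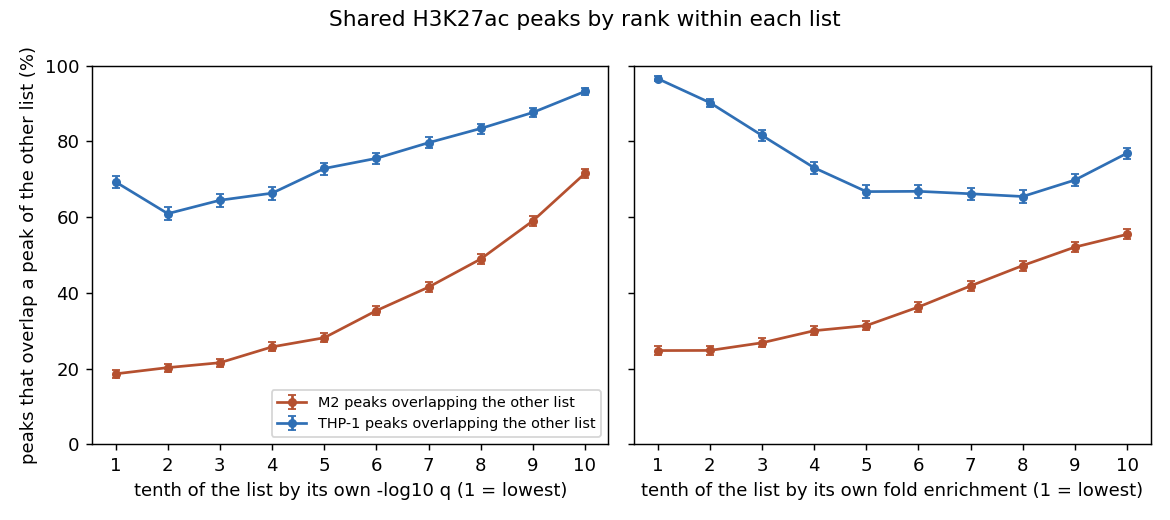
Percent of peaks (vertical axis) that overlap a peak of the other list by at least 1 bp, for each decile of the M2 and the THP-1 list (horizontal axis, lowest to highest) ranked by -log10 q (left) or fold enrichment (right), with bars for exact 95% binomial intervals. By -log10 q the M2 share climbs from 18.6% to 71.5%, and by fold enrichment the THP-1 share starts at 96.6% and reaches 65.4% in the eighth decile.

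The M2-only peak of highest fold enrichment lay on chromosome 1 at 53873489 to 53875675, 37.6-fold over background, and its nearest THP-1 peak was 79934 bp away. The next lay on chromosome 6 at 42481451 to 42483333 (36.2-fold), with a THP-1 peak 5405 bp away. The others were on chromosome 21 at 47478099 to 47482610 (34.8-fold), chromosome 18 at 21172550 to 21175200 (34.6-fold) and chromosome 5 at 36600212 to 36601331 (34.6-fold), 35580, 12322 and 55874 bp from a THP-1 peak.

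The THP-1-only peak of highest fold enrichment lay on chromosome 5 at 163390510 to 163392282 (17.1-fold), 19146 bp from the nearest M2 peak. The next was on chromosome 7 at 155786114 to 155787834 (16.2-fold), 31021 bp from an M2 peak. The remaining ones were on chromosome 17 at 21048971 to 21051423 (15.5-fold), chromosome 3 at 63663618 to 63666379 (15.3-fold) and chromosome 9 at 108519181 to 108520783 (15.2-fold). Their nearest M2 peaks were 18196, 81870 and 60932 bp away.

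The M2 list held more dense clusters of H3K27ac peaks than the THP-1 list. After neighbouring peaks were stitched, 337 M2 regions held at least 10 peaks and together 5.95 Mb of peak sequence, 9.71% of the M2 covered length. In THP-1 cells 101 regions did, with 1.61 Mb or 5.76%. THP-1 peaks covered less than 50% as much sequence as the M2 peaks in 234 of the 337 M2 regions, which is 69.4% (64.2 to 74.3), and 18 of them held no THP-1 peak. M2 peaks covered less than 50% as much in 9 of the 101 THP-1 regions, which is 8.91% (4.16 to 16.2), and covered more than the THP-1 peaks in 54. For comparison, all THP-1 peaks together covered 45.6% as much sequence as all M2 peaks. The median THP-1 coverage in the dense M2 regions was 33.5% of the M2 coverage. In M2 regions of 5 to 9 peaks, a comparison added after the data were seen, it was 31.0%, and 70.4% (68.3 to 72.4) of 1946 such regions were less than 50% as covered, a share inside the interval of the dense M2 regions. In 825 THP-1 regions of 5 to 9 peaks the share was 12% (9.86 to 14.4). Among all regions of fewer than 10 peaks it was 74.9% (74.4 to 75.5) of 25560 M2 regions, just above the interval of the dense M2 regions. For THP-1 it was 29.5% (28.8 to 30.2) of 16960 such regions. The numbers of regions depend on the stitching distance, the threshold and the number of peaks in a list. A longer list can give more dense regions for that reason alone, and they were not counted in lists of equal length. At a -log10 q of at least 10 there were 54 M2 and 7 THP-1 regions, with 81.5% and 28.6% less covered in the other list.

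The M2 region with the most covered sequence lay on chromosome 8 at 97800417 to 97941544. Its 21 M2 peaks covered 101.8 kb, and 23 THP-1 peaks in the same region covered 36.3 kb. The second, on chromosome 3 at 151910968 to 152049825, held 61.4 kb in M2 and 29.4 kb in THP-1 cells. The third, on chromosome 6 at 134640599 to 134787589, had the greatest contrast of the 5, with 32 M2 peaks over 60.5 kb and 5 THP-1 peaks over 3.32 kb, a ratio of 18.2. The regions on chromosome 8 at 125762124 to 125880826 and on chromosome 20 at 48836121 to 48970600 each held 56.6 kb of M2 peaks, against 9.96 and 10.5 kb of THP-1 peaks.

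Of the 5 THP-1 regions with the most covered sequence, 4 were covered at least as far in the macrophages. The first lay on chromosome 2 at 145400426 to 145472367, with 44.5 kb in THP-1 and 50.5 kb in M2 cells. The second, on chromosome 5 at 134731767 to 134793227, held 36.2 kb in THP-1 and 38.7 kb in M2 cells. Regions on chromosome 1 at 235043919 to 235123636 and chromosome 10 at 65216646 to 65288082 had 36.1 and 35.4 kb in THP-1 against 36.9 and 43.3 kb in M2 cells. The exception was a further region of chromosome 1, 44227899 to 44279266, where 8 THP-1 peaks covered 32.8 kb and 11 M2 peaks 10.3 kb.

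**Figure D2:**
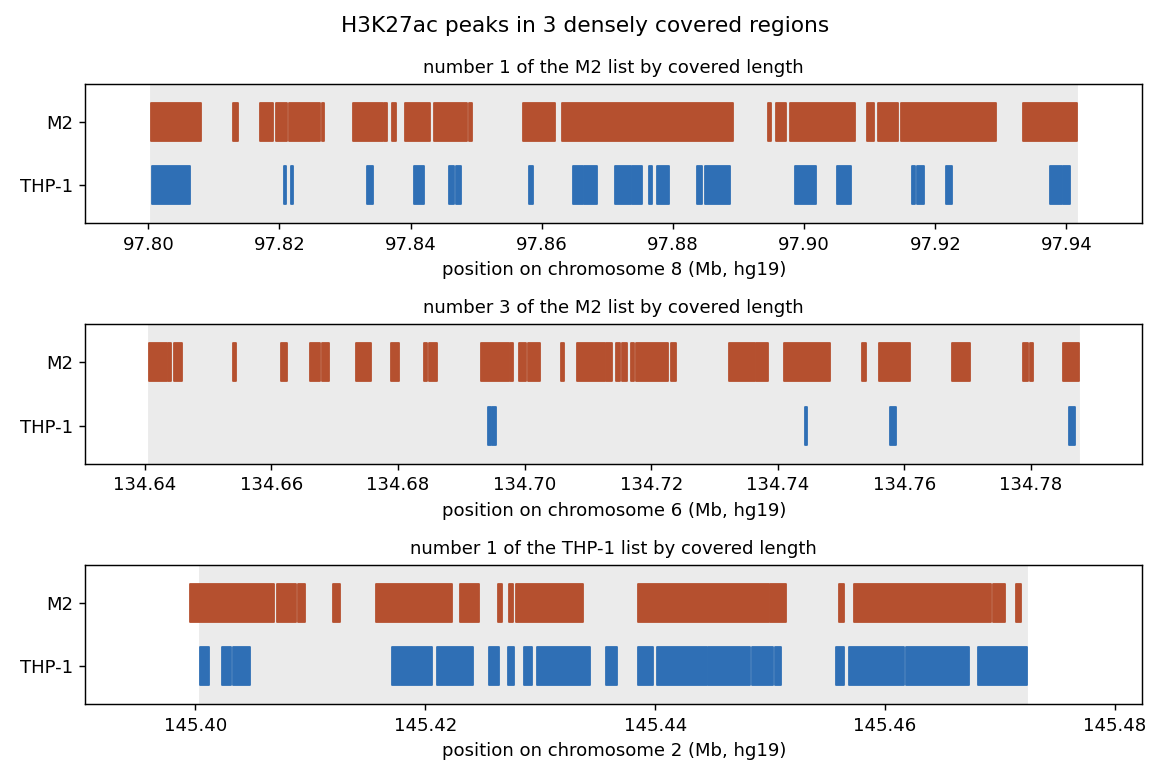
Peaks of the M2 (upper bars) and THP-1 (lower bars) H3K27ac lists, drawn to scale along chromosomes 8, 6 and 2 (position in Mb, hg19), with the stitched region shaded grey. The chromosome 8 region holds 101.8 kb of M2 and 36.3 kb of THP-1 peaks, the chromosome 6 region 60.5 and 3.32 kb, and the chromosome 2 region 50.5 and 44.5 kb.

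The background against which the peaks were called was not alike in the lists. Recovered from the same columns and divided by the lowest of its list, it had a median of 2.54 at M2 summits and 4.99 at THP-1 summits. At 15137 of the shared pairs it could be set side by side, and the THP-1 value was higher in 83.2% of them, with a median ratio of 2.12 (interquartile range 1.26 to 3.35). A higher background lowers the fold enrichment and the -log10 q of a peak with the same number of fragments. THP-1 peaks in the decile of highest background overlapped M2 peaks in 98.6% of cases (98.14 to 99.01), and those in the decile of lowest background in 40.4%. Fragments over the summit rose along the same deciles, from a median of 14 to 130, so background and signal rose together. The M2 share rose with background as well, from 21.8% to 54.9%. Background and fold enrichment are tied, since the background was solved from the fold.

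**Figure D3:**
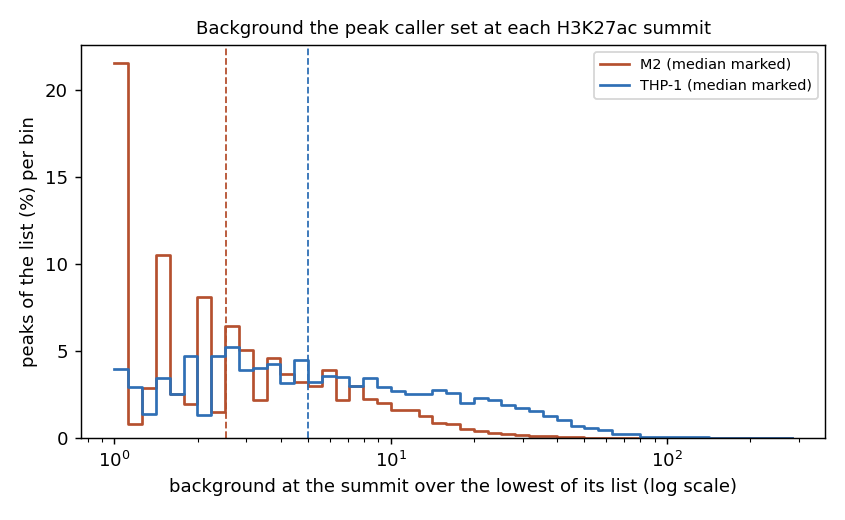
Recovered background at the summit of each peak divided by the lowest background of its list (horizontal axis, log scale), as percent of the list's peaks per bin (vertical axis), with dashed lines at the medians. The median is 2.54 for the M2 list and 4.99 for the THP-1 list.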

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

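The tests on the larger M2 list reported here were chosen only after the result was seen. So were the tests at matched background and at matched fragments for THP-1 peaks of low fold enrichment, while the test on width was set before. The background against which peaks were called is in no column of the lists and was solved from fold enrichment and p-value. Its median over the lowest of the list was 2.54 at M2 summits and 4.99 at THP-1 summits. Division by the lowest value fixes that both lie above 1, so only the difference between the lists is of interest, and it was not tested.

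The M2 list held 1.79 times as many peaks as the THP-1 list. A deeper M2 library, or uniformly weaker enrichment in the THP-1 library, as the only difference would leave only weak M2 peaks without a counterpart. In the decile of M2 peaks with the highest -log10 q, 28.5% had none and 26.5% had no THP-1 peak within 1000 bp. This argues against either as the only difference between the lists. Sites that differ between the cell types can leave strong peaks unmatched at any depth or enrichment. The shares therefore do not tell how far depth or enrichment made the M2 list longer. Higher local background at THP-1 summits, whatever library set it, remains open as a contribution, since at shared pairs, each value divided by the lowest of its list, it was 2.12 times that of M2 (median). The THP-1 background at M2-only sites cannot be recovered, because the THP-1 list holds no peak there. A difference between monocytes and macrophages also stays open, untested with 1 library each.

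THP-1 peaks of the lowest fold enrichment were shared most often. Wider peaks that overlap more easily are argued against, since among THP-1 peaks no wider than the median 95.3% (94.2 to 96.2) of those in the lowest fold decile overlapped an M2 peak, against 64.6% (63.8 to 65.4) of the others. For high local background at shared sites, the share of 98.6% in the decile of highest background nearly restates the pattern. At matched background the lower-fold peaks, which had fewer fragments, were shared less often, 69.9% against 80.5%. Neither value decides. Without matching, peaks below the median fold had a median of 52 fragments over the summit and those above it 31. Their shares were 81.5% and 68.8%. At matched fragments (median 39 on each side) the shares were 76.5% (75.8 to 77.1) and 73.9% (73.2 to 74.6). The lower-fold peaks, which had the higher background, were then shared more often in 8 of 10 deciles and less often in 2. Much of the gap therefore went with the fragments over the summit. The remaining gap may go with background. At fixed fragments, however, a lower fold is a higher background by construction, so this split cannot show background to be the cause. Why peaks of low fold had more fragments, and why shared sites had a higher background, stays open.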

How the results depend on the processing

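Among these alternatives, the background limit, sharing within 1000 bp, the chromosome 8 stretch and the local shifts were chosen after the data were seen. M2 peaks outnumbered THP-1 peaks at the stricter threshold, after merging and without the chromosome 8 stretch. The stricter threshold is no independent check of this, because the higher background at THP-1 summits lowers their -log10 q. The shared share of THP-1 peaks was a majority except in lists of 15722 peaks and with low background. At a -log10 q of at least 10 there were 34097 M2 and 13241 THP-1 peaks, 25.8% and 73.7% of them shared, and 54 and 7 dense regions, with 81.5% and 28.6% (interval 3.67 to 71.0) less covered in the other list. With background at most 2 times the lowest there were 22181 and 5842 peaks (ratio 3.80), 25.7% and 45.5% shared. This limit removes a larger share of the THP-1 than of the M2 list by construction, because background was higher in the THP-1 list. Its ratio is therefore no evidence of a larger M2 list. The shared share of M2 and THP-1 peaks was 35.9% and 72.8% with 50% of the shorter peak overlapped, 30.9% and 72.9% with the summit inside, 43.2% and 79.8% within 1000 bp, 49.0% and 59.6% in lists of 31444 peaks, and 40.5% and 48.7% in lists of 15722. A stricter threshold or shorter lists leave fewer peaks to overlap by construction, and otherwise the cause was not tested. Dense regions numbered 45 and 26 when stitched within 5000 bp and 693 and 195 within 20000 bp. Of the 37 values recomputed for these results, the remaining 10 stayed within 1.5 times the reported number or inside the 95% interval of the reported share, including the merged lists (ratio 1.74) and the lists without the chromosome 8 stretch. Local shifts raised the share expected by chance to 2.95% and 5.40%. For the 10 named peaks, 8 of 20 recomputed distances to the other list grew more than 1.5 times, in settings that only remove peaks and so do not test whether a named peak is absent from the other list. The alternatives for peak location, promoter genes, gene lists and motif share were not run, because no hg19 annotation or sequence was used here. No paired analysis was possible because no result comes from a test and each group has 1 library. Depth limits weak peaks, where a summit held as few as 9 M2 or 8 THP-1 fragments.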

Other observations

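The regions of this part were chosen after their values were seen, as was the test of the order of peaks along the chromosome, while the test of extra copies was set beforehand. M2-only peaks came in long runs, with no shared peak between them. The longest held 36 peaks on chromosome 12 from 65930056 to 66286821, with 51.8 kb covered. Next came 34 peaks on chromosome 2 from 238036467 to 238422091, 32 on chromosome 4 from 74641364 to 75024987, 28 on chromosome 11 from 78285358 to 78958371 and 24 on chromosome 8 from 139394473 to 139666985. In all, 29 runs held at least 20 M2-only peaks each, 663 peaks together.

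Chance order of single entries along the chromosome is argued against as the cause of the long runs. The longest run in any of 1000 reorderings held 32 M2-only peaks and at most 3 runs reached 20. The reorderings moved each entry separately, although neighbouring entries can be pieces of a wider region. Merging within 1000 bp left 42042 of the 56420 M2 entries, and runs of merged entries were not tested. Extra copies of these stretches in the M2 cells would raise the background there. The median background in the runs was 0.768 times that of other M2-only peaks. In the M2 list fragments over the summit also rose with background, from a median of 16 in its lowest decile to 153 in its highest. Peaks in runs and other M2-only peaks were not matched on fragments, so the lower background does not exclude extra copies. Loss of the stretches in THP-1 cells, or regions acetylated as domains in macrophages, also remain open. The THP-1 list gives no background at the M2-only peaks themselves, and THP-1-only peaks that may lie between them were not examined. That these runs are domains gained in macrophages is a hypothesis that may be examined in further libraries.

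In windows of 1 Mb, 2689 of which held a peak, M2 peaks were more numerous in 2313, equal in number in 123 and fewer in 253. The largest surplus of M2 peaks was on chromosome 1 from 59 to 60 Mb, with 74 M2 and 16 THP-1 peaks. Chromosome 8 from 29 to 30 Mb held 78 and 24, and chromosome 12 from 92 to 93 Mb held 61 and 9. The largest surplus of THP-1 peaks was on chromosome 16 from 54 to 55 Mb, with 38 THP-1 and 24 M2 peaks.

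Chromosome 8 from 86 to 87 Mb held 45 THP-1 and 32 M2 peaks. Of the THP-1 peaks there, 25 overlapped no M2 peak, and 4 of these were among the 20 THP-1-only peaks of highest -log10 q. The background at those 25 peaks had a median of 7.74 times the lowest of the list, against 2.31 at all THP-1-only peaks. The median at the 12 M2-only peaks of the same stretch was 1.76, against 2.06 at all M2-only peaks.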
